A study of Escherichia coli
Tequatrovirus T4 and Escherichia coli with 4 samples.

How the data were processed

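Ribosome profiling libraries came from Escherichia coli cells infected with bacteriophage T4, from uninfected cells and from cells that carried a plasmid with the T4 gene 60 cassette. Per the labels' protocols, infected cultures of strain MC4100 received phage at a multiplicity of infection of 10 and were harvested at 2.5, 4 or 5 min. The labels do not say which of these times each infected library holds, and the strain and medium of the plasmid culture are not given in the sources used here. The plasmid culture was induced with IPTG for 10 min. Lysates were digested with micrococcal nuclease, monosomes were collected from sucrose gradients, and RNA was cut from gels as fragments of 30 to 40 nt or as long fragments. The labels give the long class as 45-140 nt and the protocol gives it as up to 150 nt.

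The authors deposited raw counts of mapped reads per gene, with a separate table for each organism in each library. Each table held 4425 E. coli rows or 280 T4 rows, in the same order in every library. Per the submitters' processing notes, cutadapt, Bowtie and Bowtie2 were used, with no version or role named. The genome builds, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The tables carry no lengths or coordinates, so levels were compared between libraries and not between genes, and no position within gene 60 could be examined. In E. coli 26 names were repeated over 89 rows, and in T4 3 names were repeated over 8 rows. Repeated rows stayed in the totals and were not named.

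Each of the 4 groups held 1 library, so no replicate test was possible and no p-value is given. Total reads per library on E. coli and T4 genes together ranged from 1265759 to 13557452. Comparisons used the ratio of a gene's share of reads in 2 libraries, with a prior count of 0.5 added to each count and an exact conditional binomial 95% interval. Shares carry exact Clopper-Pearson 95% intervals. Intervals and detection limits (3 counts) cover counting error only, because reads copied by PCR are not independent molecules, and they say nothing about the spread between cultures. A gene was counted as higher or lower at a ratio of at least 2-fold with an interval excluding 1, among rows with at least 50 reads over both libraries. These rules, the 26 E. coli and 7 T4 gene lists and the naming rule were fixed before the data were examined.

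The planned denominator was the total of all E. coli rows, or of all T4 rows for phage genes. In the long libraries most E. coli reads lay on the transfer-messenger RNA ssrA and on rRNA, so a denominator of the 4345 protein-coding rows, without the 80 rows of non-coding RNA, was added after seeing the data. Counts over all tested rows are given on the planned scale with the coding-read split beside them. Counts and medians of E. coli gene lists and folds of named E. coli genes are on the coding-read scale. Moving a value to the planned scale adds a constant to its log2 ratio. That constant is -0.13 for infected over uninfected, 1.78 for infected over plasmid and -2.45 for 45-140 nt over 30-40 nt. A gene list is described by the median log2 ratio of its tested members and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 10 bins (4 bins for T4). These percentiles were computed with shares of coding reads, or of T4 reads for phage genes. Another scale keeps the order of the ratios but changes the matching on mean expression, and it was not run.

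The named E. coli genes were the 8 highest and 8 lowest ratios per comparison among genes with at least 200 reads in either library and an interval excluding 1, the 2 members of each list with the most reads, and lacZ, lacY, lacA and lacI. The rule was applied to protein-coding genes, a restriction made after seeing the data, and the non-coding rows it leaves out are given in the results. The named T4 genes were the 6 highest and 6 lowest ratios among genes with at least 100 reads in either infected library, the 10 genes with the most reads, and genes 60, 39 and 52. Other members of a list are named as examples chosen after their values were seen.

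Alternatives were edgeR TMM factors, DESeq2 size factors, the total of both organisms, totals without the 10 genes with the most reads, minimums of 20 or 200 reads or none, a prior count of 5 and a 3-fold rule. The calculations were tested on simulated data with 200 of the 4345 protein-coding rows changed by known folds (133 of the 280 T4 rows). The simulated counts held counting error alone, with library totals known. The numbers recovered and called below therefore leave out the spread between cultures, PCR copies and the choice of scale, and are not error rates for these libraries. For infected over uninfected, 95 of 100 genes changed 3-fold and 94 of 100 changed 8-fold were recovered, with 9 of the 200 under the read minimum, and 17 of 2708 unchanged genes were called. For infected over plasmid, 83 of 100 and 86 of 100 were recovered, with 21 of the 200 under the minimum, and 13 of 918 unchanged genes were called. For E. coli genes between size classes, 97 of 100 and 100 of 100 were recovered and 3 of 1605 unchanged genes were called. Among T4 rows 67 of 67 and 65 of 66 were recovered, with 1 under the minimum, and 0 of 134 unchanged rows were called. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 (scaling factors only), were used.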

Results

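Ribosome-protected fragments were counted in 4 libraries, with 1 library in each group. Footprints of the usual size (30-40 nt) came from T4-infected and from uninfected E. coli, and long protected fragments (45-140 nt) came from T4-infected cells and from cells carrying the gene 60 plasmid. Gene 60 encodes a subunit of the T4 topoisomerase, and its reading frame holds a gap of 50 nt that ribosomes bypass. The T4-infected 30-40 nt library held 1814855 reads on E. coli genes and 11469811 on T4 genes. The T4-infected 45-140 nt library held 4202088 and 2993255, the plasmid 45-140 nt library 1197901 and 67858, and the uninfected 30-40 nt library 13557447 and 5. Since no group had a replicate, every difference below compares libraries and has no replicate check.

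Phage genes held most gene reads in the 30-40 nt library of infected cells, but not in the 45-140 nt library. T4 genes took 86.3% of all gene reads in the T4-infected 30-40 nt library (95% interval 86.3 to 86.4%) and 41.6% in the T4-infected 45-140 nt library (41.56 to 41.64%). In the plasmid library they took 5.36% (5.32 to 5.40%), nearly all on gene 60. The uninfected library, the background, had 3 reads on ipIII and 2 on 49.2, a share of 3.69e-05%. The share in the long library rested on non-coding RNA. ssrA, the transfer-messenger RNA that rescues stalled ribosomes, made up 64.7% of E. coli reads in the T4-infected long library and 76.7% in the plasmid long library, against 7.99% in T4-infected and 0.573% in uninfected 30-40 nt footprints. rRNA made up 17.9% and 17.6% of E. coli reads in the long libraries, and 23S rRNA had 597389 and 181069 reads there against 0 in each 30-40 nt library. How reads of these multi-copy genes were assigned or removed is not stated, so this contrast is not necessarily one of fragment size. Relative to E. coli coding reads, ssrA was 44.4-fold higher in long than in 30-40 nt fragments of infected cells (interval 44.1 to 44.6) and rnpB, the RNA of ribonuclease P, was 15.5-fold higher (15.0 to 16.1). With the total restricted to T4 and E. coli protein-coding rows, a choice made after seeing the data, T4 shares were 87.4% at 30-40 nt and 81.1% at 45-140 nt in infected cells and 53.98% in the plasmid library.

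**Figure D1:**
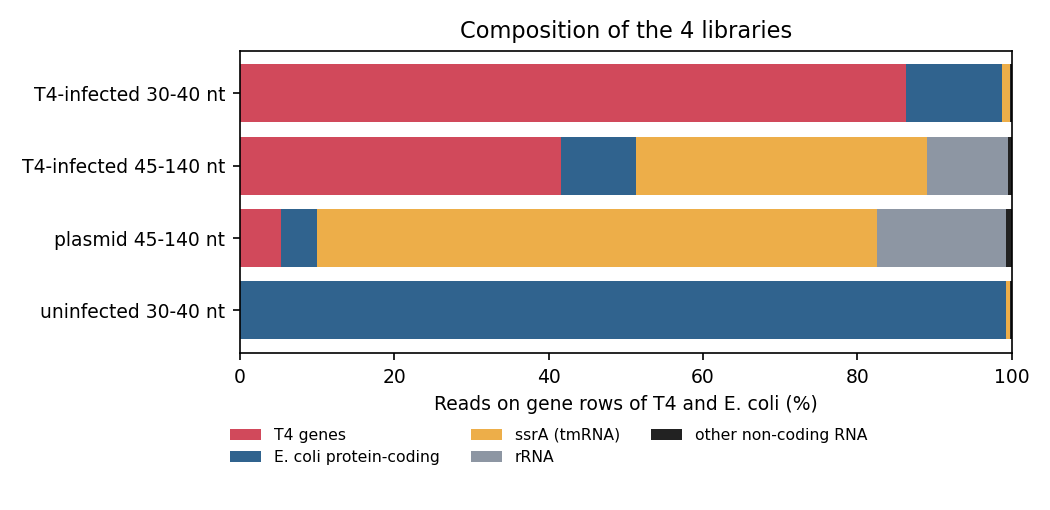
Stacked bars give the percentage of reads on gene rows of T4 and E. coli in each of the 4 libraries, split into T4 genes, E. coli protein-coding genes, ssrA, rRNA and other non-coding RNA. T4 genes hold 86.3% of the T4-infected 30-40 nt library, and ssrA holds 72.6% of the plasmid library.

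Infected and uninfected 30-40 nt footprints were compared to ask how translation of host genes differed during infection. By list median, host genes of heat shock, flagella, maltose uptake and stress had higher shares of host coding reads in infected cells. Genes of the ribosome and of cold shock had lower ones by the same measure, and not every member of a list followed its median. Among the 54 ribosomal protein genes 49 were lower and 0 higher, with a median log2 ratio of -1.78, below all 10000 random lists (percentile 0). The abundant rplL was 2.88-fold lower (interval 2.82 to 2.94) and rpsD 3.70-fold lower (3.61 to 3.80). Translation factors had 9 of 15 lower and 0 higher (median -1.03, percentile 0.795), among them the release factor gene prfC at 3.37-fold lower, while the elongation factor genes fusA and tsf were 1.46-fold and 1.40-fold lower. In contrast, 14 of 20 heat-shock chaperone and protease genes were higher and 0 lower (median 1.56, percentile 100). The small heat-shock protein genes ibpB and ibpA were 150.4-fold (107.5 to 223.6) and 28.05-fold (24.5 to 32.3) higher, the disaggregase gene clpB 15.3-fold, htpG 11.7-fold, and the chaperone genes dnaK and groL 7.93-fold and 7.39-fold. Among 8 tested cold-shock genes 4 were lower and 1 higher (median -1.28, percentile 0.510). Those for the RNA chaperone cspA and the RNA helicase deaD were 17.8-fold (15.7 to 20.4) and 15.3-fold (13.9 to 16.9) lower, and cspE was 3.16-fold lower, whereas cspC was at a ratio of 1.01 and cspD, a stationary-phase member, was 4.44-fold higher.

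Flagellar and chemotaxis genes showed the largest list median, with 16 of 18 higher and 1 lower (median 4.82, percentile 100). Of the 18, 8 had at least 50 reads in the uninfected library alone. The rest, such as flgB with 136 infected and 19 uninfected reads, reached the minimum with the help of infected reads. Since the uninfected library is the deeper one, that favors higher ratios among them and limits the list median. The flagellin gene fliC was 47.6-fold higher (42.9 to 53.1) and the hook gene flgE 57.9-fold higher (43.5 to 79.9), on 404 and 51 reads in the uninfected library. In the same pair of libraries, reads on the argF to lac region were 101-fold higher in infected cells (63.6 to 182, on 217 and 17 reads). Strain MC4100 is known to lack this region. A difference in strain or culture was therefore not separated from infection for the flagellar list or any other list of this comparison. Genes of sialic acid metabolism were also among the 8 highest, with nanC 23.4-fold, nanM 22.7-fold and yjhC 20.9-fold higher, as was ydeN at 25.6-fold. Over all rows, as a share of E. coli reads, the non-coding rdlD was the second highest of those named by the rule, at 56.8-fold (900 and 118 reads). Of the maltose genes 7 of 11 were higher and 0 lower (median 1.25, percentile 99.9), with lamB 2.58-fold and malE 1.52-fold higher. Stringent and general stress genes had 7 of 12 higher and 1 lower (median 1.16, percentile 100.0), including the ribosome hibernation genes rmf at 16.9-fold and raiA at 8.23-fold. uspA was 2.39-fold higher and dksA stood at a ratio of 0.793. Glycolysis genes had 5 of 13 higher and 0 lower (median 0.87, percentile 99.6), with gapA 2.20-fold and pgk 1.39-fold higher. Nucleotide synthesis genes had 10 of 22 higher and 2 lower (median 0.95, percentile 100.0). Its members with the most reads, purA and ndk, were 1.54-fold and 2.26-fold lower while pyrI and pyrB, of pyrimidine synthesis, were 10.2-fold and 7.84-fold higher. Methionine and arginine synthesis had 4 of 15 higher and 0 lower (median 0.61, percentile 99.4, but 96.8 with a minimum of 200 reads), with carB 7.92-fold higher, metH 1.44-fold higher and metK 1.55-fold lower. Replication and repair genes had 0 of 21 higher and 9 lower (median -0.68, percentile 2.43), with the clamp gene dnaN 3.55-fold lower, while ssb was 1.36-fold lower and gyrA 1.33-fold higher.

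The other lists lay within the middle 95% of random lists. RNA polymerase and transcription factors had 4 of 11 lower and 0 higher (median -0.87, percentile 2.72), although rpoB and rpoC each stood at a ratio of 1.22. RNA decay had 4 of 12 lower (median -0.72, percentile 5.22), with rne 2.28-fold lower, and Sec translocation 4 of 12 lower (median -0.72, percentile 5.02), with secY 1.65-fold lower. Medians and percentiles were -0.43 and 13.8 for aminoacyl-tRNA synthetases, -0.40 and 22.9 for toxins and antitoxins, 0.05 and 81.9 for the SOS response and 0.21 and 81.5 for phage-shock and envelope stress. They were 0.09 and 72.6 for outer-membrane proteins, 0.18 and 70.2 for ATP synthase, 0.26 and 84.6 for the TCA cycle, 0.33 and 84.5 for nucleoid-associated proteins and 0.10 and 78.1 for histidine, tryptophan, leucine and isoleucine-valine synthesis. Within these lists the porin gene ompF was 3.16-fold and ompA 1.62-fold higher, and recA was 1.37-fold lower. Leader peptides had a median of -0.66 (percentile 15.7) but pooled reads 5.06-fold higher, because tnaC, which controls the tryptophanase operon, was 13.9-fold higher (13.1 to 14.8) and thrL was 3.13-fold lower. The lowest ratios outside the lists were those of trmH at 25.5-fold, rhlE at 19.4-fold, yacC at 18.3-fold (4.86 to 1084, on 1 read), yhjV at 14.3-fold and nth at 10.8-fold lower, on 6 or fewer reads each in infected cells. yrbN had 0 reads there against 216, at least 8.82-fold lower. lacZ had 78 reads in infected and 7 in uninfected cells (85.4-fold, 42.1 to 233.6), lacI 18 and 2 (60.4-fold, 17.6 to 653), lacY 12 and 0 (at least 32.6-fold higher) and lacA 1 and 0.

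Over all 2928 tested rows, 441 were higher and 724 lower as a share of E. coli reads, and on protein-coding reads 464 of 2902 were higher and 628 lower. With phage reads included in the total, 34 were higher and 2723 lower. The median log2 ratio of these rows was -0.29 on E. coli reads and -3.16 with phage reads included. On that scale the flagellar list alone, of 24 lists, kept a median above 0 (1.82), and the heat-shock median was -1.43, so the directions above describe shares within host translation. ssrA had 0.0879 reads per coding read in the infected and 0.00577 in the uninfected library.

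**Figure D2:**
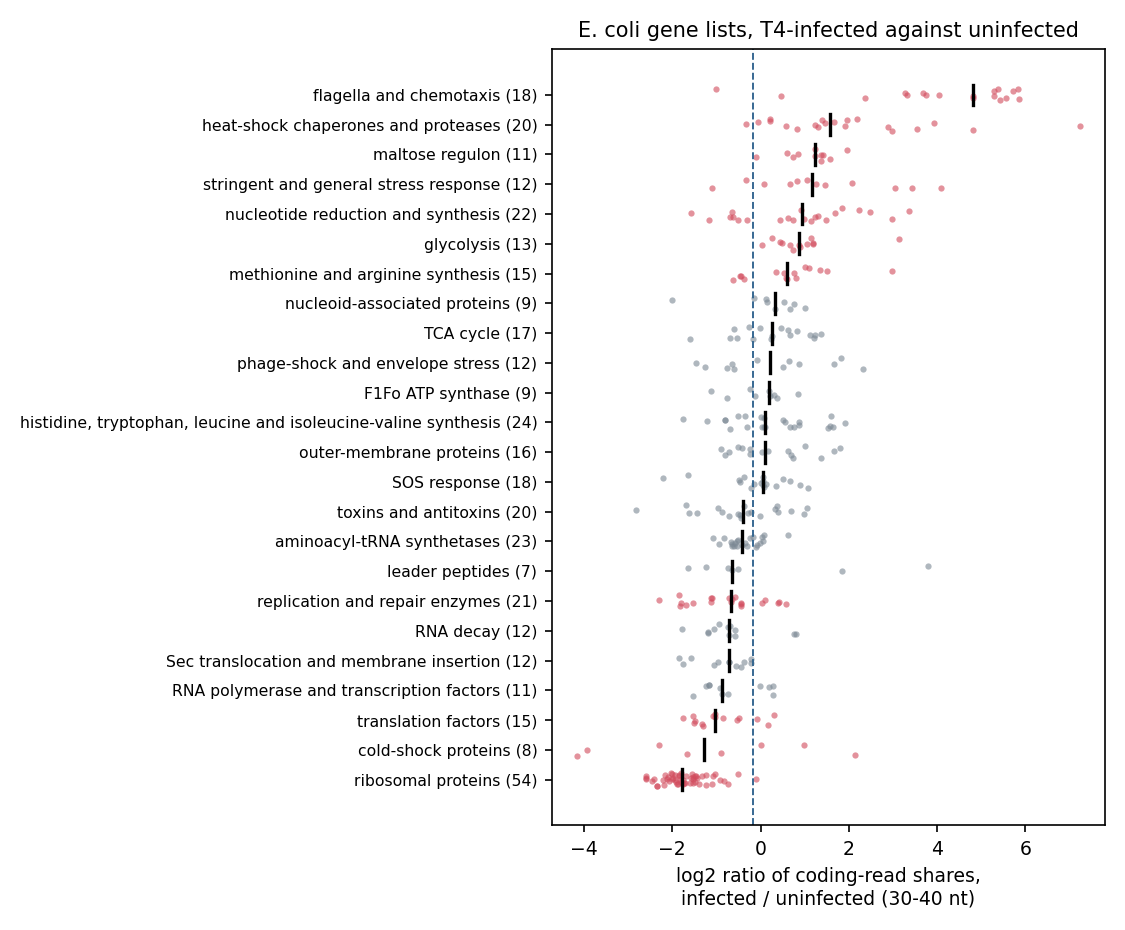
Each point is a gene of a list fixed in advance and its log2 ratio of coding-read shares, T4-infected over uninfected, at 30-40 nt; black bars mark list medians, the dashed line the median of all tested genes (-0.17), and numbers in brackets the tested members. Red lists lie outside the middle 95% of random lists, with medians from -1.78 for ribosomal proteins to 4.82 for flagella; scatter along the vertical within a list carries no value.

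The long-fragment libraries of infected cells and of plasmid-bearing cells differed in infection, plasmid, induction and possibly strain and medium, which this pair does not separate. Among the genes with enough reads to be tested, most maltose genes were higher in infected cells and those of amino acid synthesis were lower. Of 9 tested maltose genes 8 were higher (median 4.60, percentile 100, and 2.96 with the 4 genes at 0 plasmid reads set to 3 reads), and lamB and malE had 2128 and 1181 reads against 0, at least 58.9-fold and 32.7-fold higher. Of 24 genes of histidine, tryptophan, leucine and isoleucine-valine synthesis, 4 reached the minimum of 50 reads, all but hisI through their plasmid reads, and were lower (median -6.80, percentile 0.0300), with ilvC 238-fold (144 to 456) and ilvD 105-fold (60.96 to 210) lower. Methionine and arginine synthesis had 9 of 9 tested genes lower (median -4.71, percentile 0.110), with metE, a methionine synthase, 633-fold (456 to 937) and carB 51.2-fold lower. Because the minimum favors genes high in the plasmid library, rows were also chosen, after these results were seen, by at least 50 reads in the uninfected library. Methionine and arginine synthesis then had 14 of 14 lower (median -3.78, percentile 0), and the other amino acid list 14 of 24 lower and 0 higher, 19.9-fold lower in pooled reads (17.6 to 22.7), with its median of -2.00 inside the middle 95% of random lists (percentile 8.96). cspA was 498-fold lower (417 to 605) and fepA, the receptor of the siderophore enterobactin, 313-fold lower (233 to 439). yibD was 1019-fold lower on 2 reads against 211 (347 to 1.06e+04), ydcZ 483-fold and ydcY 137-fold. lacZ was 200.3-fold lower (124.7 to 365.8), lacY had 1 read against 48 (389-fold, 98.9 to 2.33e+04), lacI 3 against 11 (39.6-fold, 11.7 to 246), lacA 3 against 1 (5.16-fold, with an interval spanning 1), and betA was 51.8-fold lower.

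Several abundant host genes had 0 reads in the plasmid library. Against a floor of 3 reads, tnaA was at least 636-fold higher in infected cells, ompC at least 473-fold, ompT at least 90.8-fold, flu at least 85.0-fold, nanA at least 84.3-fold, glpT at least 76.3-fold, fliC at least 24.9-fold and tnaC at least 4.46-fold. yfiD had 1 read against 5933 (329-fold, 88.4 to 1.95e+04). The flagellar list had 2 of 9 higher and 5 lower (median -2.40, percentile 0.600), with flgE 10.3-fold lower and fliC at 0 in the plasmid library. With rows chosen by the uninfected library the flagellar list had 1 of 8 higher and 1 lower (median 0.48, percentile 99.6), so its direction depends on the filter. Ribosomal proteins had 23 of 54 higher and 5 lower (median 0.83, percentile 98.3), with rpsG 6.72-fold higher and rplL at a ratio of 1.05, but the list lay at percentile 79.6 with a minimum of 200 reads and at 25.5 with rows chosen by the uninfected library. TCA cycle genes had 12 of 16 higher and 0 lower (median 1.67, percentile 97.9), with sucB 2.13-fold and acnB 1.46-fold higher, but lay at percentiles 95.6 and 95.2 with the same alternatives. Leader peptides had 1 of 3 higher and 2 lower (median -4.15, percentile 1.57), with ilvL 81.3-fold lower, and 4 of 7 lower and 1 higher with rows chosen by the uninfected library (percentile 0.01). ATP synthase (6 of 8 higher, median 1.53, percentile 97.49), glycolysis (9 of 12 higher, median 1.53, percentile 97.1), heat shock (9 of 19 higher and 2 lower, median 0.96, percentile 96.4) and outer-membrane proteins (8 of 15 higher, median 1.17, percentile 94.4) lay within the middle 95%. In these lists gapA was 2.70-fold, groL 3.66-fold, dnaK 3.12-fold, ompF 2.71-fold, ompA 3.03-fold and atpA 2.63-fold higher. rpoS, the stationary-phase sigma factor, was 9.62-fold lower, lexA 13.9-fold, secA 4.69-fold, gyrB 4.04-fold and hfq 2.55-fold lower, in lists whose medians lay at percentiles from 6.88 to 67.9. Percentiles were 45.2 for translation factors, 81.4 for aminoacyl-tRNA synthetases, 35.2 for RNA polymerase and transcription factors, 65.3 for cold-shock genes, 53.6 for phage-shock genes, 72.3 for nucleoid-associated proteins and 38.3 for nucleotide synthesis. With rows chosen by the uninfected library, RNA decay, replication and repair, and Sec translocation lay below the middle 95% of random lists (percentiles 0.580, 0.615 and 0.640) and stress genes above it (98.2), and the maltose list stayed above (8 of 11 higher and 1 lower, median 2.39, percentile 99.9).

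As a share of all E. coli reads 712 of 1138 rows were higher and 128 lower, and on protein-coding reads 325 of 1108 were higher and 360 lower. With phage reads in the total the split was 557 to 201, and without the 10 most abundant rows 349 to 366. The median of tested coding genes was 1.72 on all E. coli reads and -0.06 on coding reads, and 8 of 23 list medians changed sign between scales, while those of the maltose, amino acid synthesis, leader peptide, flagellar, TCA and ribosomal lists kept theirs.

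Long and 30-40 nt fragments of infected cells were compared to ask which genes were unequally represented among long protected fragments. For most host genes the shares of coding reads were alike, with r = 0.943 between the libraries across 2201 coding genes, which are not independent replicates. The elongation factor Tu genes tufB and tufA were 54.4-fold (51.03 to 58.0) and 20.7-fold (19.9 to 21.6) higher among long fragments. These are near-identical copies, and how reads shared by them were counted is not stated, so both values are uncertain. yfiD, a stress-induced glycyl radical protein, was 49.2-fold higher (43.7 to 55.7), followed by hinT at 3.71-fold, rpsQ at 2.998-fold, nuoK at 2.64-fold, ibpB at 2.45-fold and rplD at 2.33-fold. The entericidin gene ecnB was 9.56-fold lower (5.35 to 21.2), rpmJ 7.62-fold (6.04 to 9.88), tnaC 7.36-fold (6.29 to 8.70) and cspC 4.58-fold (4.24 to 4.96), beside plsX at 9.90-fold, gtrS at 4.42-fold, ompW at 3.87-fold and ybfA at 3.85-fold lower. Over all rows, as a share of E. coli reads, the 8 highest ratios were those of 16S and 23S rRNA rows, and the non-coding rdlD (6 against 900 reads) and tff (22 against 240) were among the 8 lowest.

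Translation factors had 3 of 15 higher and 0 lower (median 0.22, percentile 99.5), led by tufA and tufB, with fusA at a ratio of 1.20. The uncertainty of the tufA and tufB values carries over to this list, which was not recomputed without them. Nucleoid-associated proteins had 2 of 9 higher (median 0.46, percentile 99.5), with hns at a ratio of 1.42 and hupB at 0.793, and toxins and antitoxins 2 of 5 higher (median 0.70, percentile 99.2). Aminoacyl-tRNA synthetases had 0 of 23 higher or lower, with a median of 0.11 at percentile 98.1. Outer-membrane proteins had 3 of 16 lower and 0 higher (median -0.43, percentile 0.695), among them lpp at 2.19-fold lower, while ompF and ompA stood at ratios of 0.808 and 0.740. The ribosomal protein list (3 of 54 higher, 6 lower) had a median of -0.11 at percentile 54.9, although rplL was 1.98-fold higher, and the heat-shock list a median of -0.16 at percentile 42.7, with groL at a ratio of 1.19 and dnaK at 0.803. The flagellar list (3 of 16 higher) had a median of 0.17 at percentile 96.6 and the maltose list (0 of 10) one of -0.38 at percentile 8.38. raiA and cspE were 2.88-fold and 2.62-fold lower. Medians of the remaining lists lay between percentiles 14.3 and 89.9. lacZ had 16 reads against 78 (2.01-fold lower, 1.19 to 3.78). lacI had 3 against 18 (2.23-fold lower, 0.740 to 13.4), lacY 1 against 12 (3.52-fold lower, 0.750 to 217) and lacA 3 against 1 (5.52-fold higher, 0.570 to 373).

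As a share of all E. coli reads 29 of 1862 rows were higher and 1798 lower. On protein-coding reads 86 of 1820 were higher and 146 lower, with TMM or DESeq2 factors 137 higher and 117 lower, and with phage reads in the total 67 higher and 369 lower. The median log2 ratio of tested rows was -2.61 on all E. coli reads and -0.03 with TMM factors, and that of coding rows was -0.16 on coding reads. On all E. coli reads every list median was below 0, so the list results above rest on the coding-read scale. Across 3 E. coli comparisons, 23 of 71 list percentiles lay outside the middle 95%. Independent lists of unrelated genes would give 3.55. Members of a list can share an operon and the comparisons share libraries, so 3.55 is not a chance level for these lists.

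The holin gene t was the phage gene with the highest ratio of long to 30-40 nt fragments. It had 15698 reads in the long library and 27 in the 30-40 nt library, a 2187-fold higher share of T4 reads (interval 1531 to 3382). The row T4s002 was 42.7-fold higher (39.8 to 45.9), the baseplate gene 11 was 17.1-fold (13.97 to 21.3), stp 8.51-fold, ndd.4 8.48-fold and nrdC.2 6.25-fold higher. The labels do not say whether the 2 infected libraries share a harvest time, so differences between size classes, here and for host genes, are not separated from differences in time after infection. Lowest among long fragments were trna.4 at 5.65-fold (5.14 to 6.25), rI.-1 at 4.81-fold, ndd.2 at 4.19-fold, motA.1 at 4.05-fold, the anti-restriction gene arn at 3.93-fold and ndd.3 at 3.89-fold lower. By the size rule 25 of 267 rows were higher and 37 lower as a share of T4 reads, and 7 and 148 with host reads in the total. The genes with the most reads differed less. ipIII, an internal head protein gene, stood at a ratio of 0.906, rIIB at 0.831, rIIA at 0.743, motB at 0.623, goF at 0.593, e.6 at 0.669, rnlB at 0.625 and nrdC.5 at 1.41. Gene 32, the single-stranded DNA-binding protein, stood at 0.716 and gene 45, the sliding clamp, at 0.870.

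Gene 60 was compared between size classes because of the coding gap in its message. It had 108007 reads at 30-40 nt, 0.942% of T4 reads (interval 0.936 to 0.947%), and 39771 at 45-140 nt, 1.33% (1.32 to 1.34%). Its share was 1.41-fold higher among long fragments (1.39 to 1.43), which ranked 68 of 267 T4 rows. As a share of all gene reads of both organisms the ratio was 0.680, the opposite direction. The other topoisomerase subunit genes, 39 and 52, stood at 2.20-fold lower (2.16 to 2.24) and 1.24-fold higher (1.23 to 1.25). In the plasmid library gene 60 had 67694 reads, 99.8% of T4 reads and 1.17 reads per E. coli coding read. The uninfected library had 0, which allows at most 2.21e-05% of its reads.

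Reads on T4 gene classes were set side by side to describe the stage of infection. Replication and recombination genes held 16.3% of T4 reads at 30-40 nt and 14.1% at 45-140 nt, early regulation and host takeover genes 17.5% and 15.5%, and nucleotide metabolism genes 12.3% and 12.6%. Topoisomerase genes held 2.93% and 3.03%, and the late transcription regulators 2.80% and 2.65%, mostly gene 45, which is also counted among the replication genes. The 47 rows of late head and tail genes together held 0.485% and 0.526%, of which alt, an ADP-ribosyltransferase carried in the virion, made up 36065 of 55577 and 9355 of 15730 reads. The lysis genes e and t held 0.0132% and 0.547%, with t behind the difference. Counting intervals were within 0.06 percentage points of each class share. Between size classes the replication list had 1 of 19 higher and 4 lower (median -0.48, percentile 0.9), early genes 3 of 24 higher and 2 lower (median -0.22, percentile 17.5) and late structure genes 3 of 36 higher and 1 lower (median 0.22, percentile 97.3). Nucleotide metabolism, late regulators and topoisomerase lay at percentiles 36.6, 51.4 and 75.9, and rows in no list held 54.04% and 56.8% of reads. Some rows are in more than 1 class, so the class shares overlap and are not separate parts of the total.

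**Figure D3:**
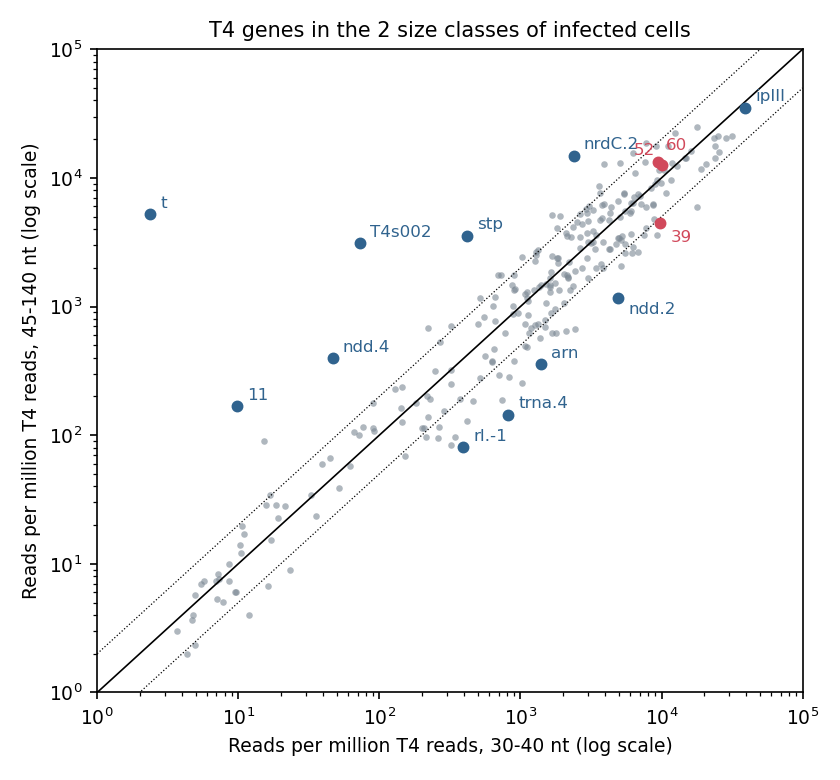
Each point is a T4 row with its scaled share of T4 reads at 30-40 nt (horizontal, log scale) and at 45-140 nt (vertical, log scale) in infected cells; the solid line marks equal shares and dotted lines 2-fold differences. Genes 60, 39 and 52 are in red and other named genes in blue, with t at 27 and 15698 reads far above the line.

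The 2 infection comparisons were set against each other to ask whether host genes differed alike in both size classes. Across 1098 genes their log2 ratios correlated weakly (Pearson r = 0.168, Spearman rho = 0.188), and 57.0% of genes lay on the same side of both medians. The ratio of long to 30-40 nt fragments in infected cells and the ratio of the plasmid to the uninfected library correlated at r = 0.171 (rho = 0.152) across 1798 genes. These values are across genes, which are not independent replicates, and each second ratio also carries the difference between the plasmid-bearing culture and the others. With a minimum of 200 reads the 2 r values were 0.246 across 459 genes and 0.183 across 892 genes. The plasmid library had r from 0.456 to 0.506 against the other libraries, while the T4-infected 30-40 nt and uninfected libraries correlated at 0.857. With 57845 coding reads in the plasmid library, counting error also lowers its correlations. How much of the difference this makes up was not tested.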

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

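The tests of explanations here and under the other observations were chosen after the results were seen. With 1 library per group no check for an unusual library was possible, and no other split of the libraries exists.

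Flagellar, methionine and arginine, and ribosomal protein lists lay on opposite sides of all genes in the infection comparisons of the 2 size classes, and the differences were not tested. Relative to the median of all genes, the flagellar list stood at 4.99 for infected over uninfected at 30-40 nt and at -2.34 for infected over plasmid at 45-140 nt, a gap of 7.33 on the log2 scale. The methionine and arginine list stood at 0.79 and -4.65, a gap of 5.44. The ribosomal list stood at -1.60 and 0.89, a gap of -2.49. With a minimum of 200 reads the ribosomal list stood at 0.05 in the second comparison. For rows with at least 50 reads in the uninfected library it stood at 1.61 there, but at percentile 25.5 of random lists matched on expression, so it did not stand apart from comparable genes. The flagellar list then stood at 1.26 and the methionine and arginine list at -3.00, so the side of the flagellar list depends on that choice. The second comparison has the plasmid culture as its reference, so these gaps also hold the differences between the uninfected and the plasmid culture.

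In the plasmid library, which carried no phage, rIIA.1 had 148 reads and 60.1 had 15, against 0 each in the uninfected library. All other T4 rows apart from gene 60 had at most 1 read in the plasmid library. In the order of the tested T4 rows, rIIA.1 and 60.1 stand directly before and after gene 60. No coordinates were available to place these reads relative to the cassette.

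In infected 30-40 nt footprints heat-shock genes were higher and ribosomal protein genes lower as a share of host coding reads. A wrong scaling factor moves all genes alike and cannot part the 2 lists, whose medians differed by 3.34 on the log2 scale. The lower depth of the infected library was tested by thinning the uninfected library to the same number of coding reads. The heat-shock median then stood 1.80 above that of all genes and the ribosomal one at -1.61 relative to it, so the pattern remained at equal depth. Random thinning keeps each gene's expected share, so it covers counting error and no other effect of depth. Whether infection or another difference between the 2 cultures lies behind the pattern cannot be told apart with 1 culture each. The long-fragment comparison with the plasmid culture gave a heat-shock median of 0.96, in the same direction but at percentile 96.4, and 0.73 at percentile 84.5 with rows chosen by the uninfected library. A difference in temperature, handling or another condition between the cultures may contribute and was not tested. Cold-shock genes differed among themselves. cspA was 17.8-fold, deaD 15.3-fold and cspB 4.93-fold lower. cspC stood at a ratio of 1.01 and cspG at 1.99, and cspD, a stationary-phase member, was 4.44-fold higher. The list was not sorted by response to temperature, so these values neither single out temperature nor argue against it.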

How the results depend on the processing

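Among alternative values of the main results, 55 stayed within counting error, within 1.5 times a count or within 0.1 of a correlation, 56 did not and 1 changed direction. Among the 55, the number of lists outside the middle range under TMM factors was carried over from the main setting and not recomputed. Where no reason follows from the setting itself, the cause was not tested. No paired analysis was possible because the groups share no replicate numbers and hold 1 library each, and leaving out replicates could not be run for the same reason. The plasmid library had the fewest coding reads of all libraries, 57845, so depth is a limit of the plasmid comparison. The protein-coding settings, and the choice of rows by the uninfected library for infected over plasmid, were added after seeing the data.

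For infected over uninfected, with 441 higher and 724 lower, phage reads in the total gave 34 and 2723. A minimum of 200 reads gave 253 higher, no minimum 679 higher, and the 3-fold rule 259 higher and 310 lower. For infected over plasmid, with 712 and 128, phage reads in the total gave 201 lower, leaving out the 10 most abundant rows gave 349 and 366, and protein-coding rows 325 and 360. A minimum of 20 reads gave 232 lower, one of 200 gave 380 and 32, and no minimum gave 342 lower. For long over 30-40 nt fragments, with 29 and 1798, TMM factors gave 137 and 117 and DESeq2 factors 137 and 117. Phage reads in the total gave 67 and 369, leaving out the 10 most abundant rows 58 and 617, and protein-coding rows 86 and 146. A minimum of 20 reads gave 44 higher, one of 200 gave 897 lower, and no minimum 51 and 2949. For T4 genes, with 25 and 37, host reads in the total gave 7 and 148 and the 3-fold rule 10 and 11. Higher minimums and stricter fold rules lower counts by construction, and non-coding reads in the total shift all genes by a constant.

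The gene 60 ratio of 1.41 was 1.43 with TMM factors, 1.31 without the 10 most abundant T4 genes, and 0.680, in the opposite direction, with both organisms in the total, where the ssrA and rRNA reads of the long library enter. The T4 share moved to 90.4% (T4-infected 30-40 nt), 79.6% (T4-infected 45-140 nt) and 53.7% (plasmid) without the 10 most abundant E. coli rows. Without rRNA it was 46.5% and 6.43% in the long libraries, and over protein-coding rows 87.4%, 81.1% and 53.98%. Without ipIII, the class shares at 30-40 nt were 18.2% (early), 16.98% (replication), 12.7% (nucleotide), 2.91% (late regulators), 3.05% (topoisomerase) and 0.504% (late structure). At 45-140 nt they were 16.02%, 14.6%, 13.03%, 2.74%, 3.14% and 0.545%, and 0.567% for lysis, as a smaller total requires.

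At a minimum of 200 reads 3 list results came to lie within the middle 95% of random lists (methionine and arginine for infected over uninfected, ribosomal proteins and the TCA cycle for infected over plasmid) and the flagellar list for size class came to lie outside. For 7 list results fewer than 3 members had 200 reads, so this was not run, among them histidine to valine synthesis and leader peptides for infected over plasmid and toxins for size class. The other 66 of those run stayed inside or outside as before, although aminoacyl-tRNA synthetases (0.28 to -0.55), cold-shock genes (0.48 to -0.35) and nucleoid-associated proteins (0.50 to -0.38), for infected over plasmid, and nucleotide synthesis (-0.01 to 0.18), for size class, crossed the median of all genes. With rows chosen by the uninfected library 24 list results instead of 23 lay outside the middle 95%. For infected over plasmid the ribosomal, TCA cycle and histidine to valine lists came to lie inside, RNA decay, replication, Sec translocation and stress lists outside, and the flagellar list moved from below to above.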

Other observations

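The siderophore receptor gene cirA and entB, of enterobactin synthesis, were 81.0-fold (66.1 to 101) and 66.6-fold (48.1 to 96.2) lower in infected than in plasmid long fragments, beside fepA. Between infected and uninfected 30-40 nt footprints cirA, entB and fepA were 5.47-fold, 4.62-fold and 4.09-fold higher in infected cells. The manganese-dependent ribonucleotide reductase genes nrdF and nrdE were 122-fold (69.9 to 251) and 27.3-fold (16.8 to 46.6) lower in infected than in plasmid cells, and 2.82-fold (1.76 to 4.29) and 5.56-fold (4.03 to 7.58) higher in infected than in uninfected 30-40 nt footprints. In infected over uninfected footprints the lactate dehydrogenase gene ldhA was 8.04-fold higher, the glycine cleavage genes gcvP and gcvH 7.93-fold and 8.13-fold, and tnaA, tryptophanase, 7.36-fold. In the same pair obgE, a ribosome assembly GTPase gene, was 9.53-fold lower (8.07 to 11.4). The 58 repeated rows of insertion sequence genes together had 8 reads at 30-40 nt and 564 at 45-140 nt in infected cells, a 157-fold higher share (84.1 to 388). How reads shared by such copies were counted is not stated, and the treatment of shared reads can differ between libraries, so this ratio is not taken as one of fragment size. The toxin gene yafQ was 10.8-fold higher (5.77 to 23.8) in the same comparison. These genes, and the tests below, were chosen after the values were seen.

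MC4100 is known to lack the region from argF to lac, yet its 20 listed genes had 217 reads among 1648220 coding reads in the T4-infected 30-40 nt library and 67 among 696404 in the T4-infected 45-140 nt library, against 17 among 13447798 in the uninfected library. Carry-over from the plasmid library, with 439 reads among 57845, was tested by scaling that library to the 78 lacZ reads. Of its 20 most abundant coding genes 4 fell under 50% of the reads so implied, with cspA at 233 against 1407 and metE at 82 against 502, and codA of the region had 32 reads against 1.14, which argues against it as the whole source. RNA of a strain that carries the region stays open. The ratio between the infected libraries was 0.735 (0.547 to 0.965), which does not exclude it, but high shares in both were what prompted the test, so the value does not favor it either.

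Of 294 genes expected at 30 or more reads in the plasmid library from their share in the uninfected library, 17 had 0 reads. Shallow depth of the plasmid library does not account for this, since ompC alone was expected at 939 reads and the 17 genes at 2548 together. A culture of the E. coli B lineage, known to lack lon and ompT, stays open. ompT is among the 17 genes and so is no test of it. lon, which is not, had 1 read against 40.7 expected, but a single gene whose count has an upper bound of 5.57 does not decide. The growth medium cannot be told apart from strain, plasmid and infection. Among 38 genes of the amino acid synthesis lists with at least 50 reads in the uninfected library, 28 were lower in infected than in plasmid cells and 0 higher. Of the 17 genes, tnaA, glpT, lamB, malE and nanA serve carbon source uptake or use. Others are not genes of that kind, among them ompC, with the most expected reads, ompT, flu and the ribosomal protein genes rplY and rpmE. These are examples, and the 17 genes were not all sorted by function.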
